A study of Mus musculus with 16 samples.

How the data were processed

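Total RNA was isolated from N25/2 cells with silica columns, and 250 ng per sample were turned into biotinylated sense-strand cDNA and hybridized to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited table holds log2 values that the authors made with robust multi-array average (RMA), per the submitters' processing notes, which name RMA and limma without versions. It has 35556 rows and 16 columns, no missing value and no pair of identical columns. Which background and summary settings the authors chose is not stated. No further normalization was applied before the tests.

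Rows were named through the platform's gene annotation, which lists 23410 of them, 21789 with 1 gene symbol and 1621 with several. The other 12146 rows are unnamed here, and 6617 of these carry numbers below the lowest named row. Symbols were updated through Entrez identifiers with a current gene table of no stated build, which held 21698 of the 21789 identifiers; for the other 91 the annotation's symbol was kept. Rows with several symbols and unnamed rows were left out of the tests. Of genes with several rows (999), the row with the highest mean over all arrays was kept, which left 19938 genes, 379 of them with an SLC symbol.

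Samples were grouped by treatment and hours as the labels give them. At 5 h, 4 deprived and 4 control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold 0.05 over all genes). The arrays of 1, 2, 3 and 16 h were compared as log2 differences of 1 array each without a test, with genes counted from an absolute difference of 1, and their mean over the 4 times was tested in limma with time as a factor. For each list and time, the median difference was placed among 10000 random lists of the same size, matched on level in 20 bins. Data handling and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

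Gene lists were written from general knowledge before the data were examined, as were the main tests, the alternatives and the rule for named genes, except where the text says otherwise. The 47 lists cover the amino acid response, tRNA synthetases, metabolism, stress responses, growth and cell cycle, other cell types and SLC families, and each had at least 5 measured members. They were tested at 5 h with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Some well-known members were not analysed here because their rows carry several symbols or none.

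The rule for named genes took, at 5 h, the 10 largest rises and the 10 largest falls past the threshold. It took the same numbers among SLC genes and up to 4 members past the threshold of each list described. At each time with 1 array per group it took the 5 largest rises and 5 largest falls among genes above the median level. The genes Atf4, Ddit3, Asns, Trib3, Chac1, Atf3, Sesn2, Ddit4, Slc7a11, Slc38a2, Slc7a5, Slc3a2, Slc7a1 and Slc7a3 were always named. Further SLC genes of the amino acid list that passed, Slc38a1 and Slc3a1, were named after their values were seen.

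Both groups carry the numbers 1 to 4 at 5 h, and the labels give no reason for the numbers. Deviations from the group means correlated between control and deprived arrays of the same number with 0.354, 0.584, 0.467 and 0.896, all above 0.1, so the numbers were treated as pairs and a fit with the number as a block was run beside the main one. This pairing comes from number 4 against the rest: among numbers 1 to 3 alone the same-number correlations were 0.193, -0.003 and -0.2.

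The alternatives were the replicate block, another quantile normalization, centring on array medians, genes above the median level only, the mean of a gene's rows, all 16 arrays in the fit, a trended and robust variance prior, array weights, each 5 h array left out in turn, unnamed rows included, and a 1.5-fold minimum. With all 16 arrays, the single arrays add no spread, so the gene results at 5 h equal the main ones by construction. Leaving out both arrays numbered 4, and camera with an estimated correlation in the blocked fit, were added after the data were seen. The methods were tested on simulated data with the real genes' levels and spread. The simulated genes varied independently of each other, with no array or pair effect and the same change at all times, unlike the real arrays. In the 5 h design 51.3 percent of 80 genes changed by 0.5 on the log2 scale were recovered, 96.3 percent of 80 changed by 1 and 100 percent of 40 changed by 2, with 12 false calls (7.06 percent of calls). With the block these shares were 31.3, 95 and 100 percent, and for the mean over the times with 1 array per group 27.5, 95 and 97.5 percent. A list of 30 genes shifted by 0.5 was called by camera and 0 of 40 unshifted lists were. Since the simulated genes were not correlated, this cannot show how often camera calls unshifted lists in the real arrays. For arrays the number of samples, 4 per group at 5 h and 1 at the other times, limits the precision.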

Results

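Gene expression was measured in N25/2, an immortalized line of mouse embryonic hypothalamic cells, after culture with amino acids (control) or without them (deprived). Whole-transcript arrays were run on 16 samples, with 4 control and 4 deprived samples at 5 h. At 1, 2, 3 and 16 h there was 1 control and 1 deprived sample, so the differences at those times had no replicate check. The title of the series names the expression of solute carrier (SLC) genes, which code for membrane transporters, under amino acid starvation as its subject. Deposited log2 values ran from 3.07 to 14.2, array medians lay between 7.02 and 7.12, and the number of arrays limits the precision. Changes below are deprived minus control on the log2 scale, or folds, with the standard error (SE) of limma's fit and n = 4 arrays per group at 5 h. The labels do not say whether the 4 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

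The first question was which genes differed after 5 h without amino acids. The amino acid response, the program that the transcription factor Atf4 drives when amino acids run short, was higher in deprived cells. Trib3, a pseudokinase gene of that program, rose 5.74-fold (log2 2.52, SE 0.12), from a log2 level of 8.11 (SD 0.18) to 10.63 (SD 0.18). Chac1, which codes for a glutathione-degrading enzyme, rose 4.35-fold (log2 2.12, SE 0.10), Cth, the enzyme that makes cysteine from cystathionine, rose 4.68-fold (2.23, SE 0.15), and Gpt2, a mitochondrial alanine aminotransferase, rose 4.29-fold (2.10, SE 0.09). Of the 32 measured genes of this list, 27 rose, none fell, and the median change was 1.10.

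Among the regulators in that list, Atf4 itself rose by 0.95 (SE 0.08) and Ddit3, which codes for the transcription factor CHOP, by 1.77 (SE 0.14). Atf3, a stress-induced transcription factor with its lowest value on control array 4, rose by 1.84 (SE 0.21). Sesn2, a leucine-binding inhibitor of the kinase complex mTORC1, rose by 1.85 (SE 0.13), and Ppp1r15a, which codes for a phosphatase subunit acting on eIF2alpha, by 1.79 (SE 0.14). Asns, asparagine synthetase, was already at a level of 11.85 (SD 0.19) in control cells and rose by 1.01 (SE 0.12). The 5 list members that did not pass, named after their values were seen, were Niban1, Map1lc3b, Fgf21, Cdsn and Ddit4. Ddit4, an inhibitor of mTORC1, differed by 0.64 (SE 0.35) with an adjusted p = 0.538 in limma, and passed with the replicate number as a block (adjusted p = 8.79e-05); over all settings its adjusted p ran from 8.79e-05 to 0.853. Its difference was 0.36 without deprived array 4 and 0.98 without control array 4. Ddit4 was highest on array 4 in both groups (10.14 in control and 10.59 in deprived cells). Without both of these arrays its difference was 0.70 (adjusted p = 0.000185 in limma).

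Other large rises were Slc7a11 (9.22-fold), Ciart, a circadian repressor gene (4.99-fold; log2 2.32, SE 0.17), and Gpr141, which codes for an orphan receptor (4.70-fold; log2 2.23, SE 0.32). The largest falls were smaller. Has2, hyaluronan synthase, fell by 1.46 (SE 0.30), Phlda1, a growth-factor-induced gene, by 1.41 (SE 0.21), and Chst12, a chondroitin sulfotransferase, by 1.14 (SE 0.09). Lfng, which modifies Notch receptors, changed by -1.07 (SE 0.10), Sync by -1.06 (SE 0.08), Tubb2a, a tubulin gene, by -1.05 (SE 0.23) and Castor2, which codes for a homologue of an arginine sensor of mTORC1, by -1.02 (SE 0.15). Tgfb1i1 changed by -0.99 (SE 0.09), Ccne1, cyclin E1, by -0.98 (SE 0.11) and Fhl3 by -0.96 (SE 0.08).

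Over all 19938 genes, 820 passed an adjusted p of 0.05 in limma, 481 higher and 339 lower in deprived cells. Of these, 80 were at least 2-fold higher and 7 at least 2-fold lower. Both arrays numbered 4 stood apart from the other 5 h arrays, and the count was 3632 with the replicate number as a block (1639 higher, 1993 lower) and 2695 without both of them. All 820 genes were among the genes called in each of these settings. With any of the arrays numbered 1 to 3 left out, it was 486, 424 and 521 for the controls and 382, 424 and 431 for the deprived arrays.

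Of 18 measured cytosolic tRNA synthetase genes, whose products charge transfer RNAs, 12 rose and none fell, with a median change of 0.68; with the replicate block 14 were higher and 1 lower. Cars rose by 1.32 (SE 0.13), Tars by 1.15 (SE 0.11), Yars by 1.04 (SE 0.10) and Gars by 1.01 (SE 0.09). None of the 16 mitochondrial synthetase genes passed, against 2 lower with the block, and their median change was -0.01. Of 14 genes of serine, glycine and one-carbon metabolism, 7 rose, with a median of 0.43, among them Mthfd2 by 1.35 (SE 0.15), Aldh1l2 by 1.08 (SE 0.15), Psph by 0.99 (SE 0.10) and Shmt2 by 0.83 (SE 0.13). With the block 8 of these genes were higher and 1 lower.

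In 6 other lists fewer members rose and none fell. Of 33 lysosomal genes 5 rose, among them Fnip1 by 0.83 (SE 0.08) and Flcn by 0.68 (SE 0.10), whose products act together on the nutrient-sensing Rag GTPases, Gla, a lysosomal galactosidase, by 0.66 (SE 0.09), and Rragc, a Rag GTPase, by 0.64 (SE 0.11). Of 29 autophagy genes 6 rose, among them Gabarapl1 by 0.89 (SE 0.09), Atg12 by 0.58 (SE 0.13) and the cargo receptor Sqstm1 by 0.53 (SE 0.08). With the block, 12 lysosomal genes were higher and 2 lower, and 13 autophagy genes were higher and 1 lower. Of 15 clock genes 3 rose, Ciart, Nr1d2 by 0.93 (SE 0.08) and Cry2 by 0.41 (SE 0.10), and 6 were higher with the block. Of 16 hypoxia target genes 3 rose, Ero1a, an oxidase of the endoplasmic reticulum, by 1.56 (SE 0.27), Vegfa, a vascular growth factor gene, by 1.32 (SE 0.10) and Ndrg1 by 0.60 (SE 0.08), while the list's median change was 0.03; 5 were higher with the block. Of 44 ribosome biogenesis genes 4 rose, Nop14 by 0.79 (SE 0.14), Wdr43, Utp14a and Pes1, with a median of 0.19, and 21 were higher and 2 lower with the block. Of 23 translation factor genes 4 rose, among them Eif4ebp1, a translation repressor, by 0.95 (SE 0.16) and Eif2s2, a subunit of eIF2, by 0.79 (SE 0.14), and the list's median change was 0.015. Cars, Sqstm1, Ndrg1, Eif4ebp1, Herpud1 and Sesn2 belong to the amino acid response list as well.

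Genes of the endoplasmic reticulum stress response went both ways. Of 23 genes, 3 rose, including Herpud1 by 1.37 (SE 0.07) and Dnajb9 by 1.13 (SE 0.16), and 4 fell, including Sec61b by 0.55 (SE 0.10) and Sec24d by 0.42 (SE 0.10), components of protein translocation and of vesicle coats. With the block, 4 were higher and 11 lower. Of 28 genes of eIF2alpha kinases and nutrient sensing, 3 rose, among them Sesn2 and Lars (0.77, SE 0.17), and 2 fell, Castor2 and Sesn1 (-0.73, SE 0.16); with the block, 7 were higher and 7 lower. Of 20 cholesterol synthesis genes Dhcr7 (-0.66, SE 0.07) and Mvk (-0.46, SE 0.11) fell, with a list median of -0.27. The mean level of this list was 10.08 on control array 4 and 9.37 to 9.57 on the other control arrays, against 9.29 to 9.44 on the deprived arrays. Of 15 fatty acid synthesis genes Fasn and Elovl6 fell, each by 0.52 (SE 0.08 and 0.10). With the block 8 cholesterol and 7 fatty acid genes were lower, and none of either was higher; without both arrays numbered 4, 3 cholesterol genes were higher and 5 lower, and 4 fatty acid genes lower. None of 15 glycolysis genes passed, against 2 higher and 2 lower with the block.

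Limma's camera, which sets each list against all other genes, called 16 of the 47 lists with its preset correlation. The amino acid response list (adjusted p = 3.75e-60) was the only list called with an estimated correlation (adjusted p = 0.00745), and with that and the block together its adjusted p was 0.17. The adjusted p with an estimated correlation was 0.105 for the cytosolic synthetases, for serine and one-carbon metabolism and for the clock genes, 0.136 for fatty acid synthesis, 0.426 for the lysosome and 0.588 for autophagy. It was 0.575 for ribosome biogenesis, 0.664 for hypoxia targets, and 0.67 for cholesterol synthesis and for translation factors. Of 20 alternative settings 10 kept the translation factor call, 14 the cholesterol call and 16 the hypoxia call. The translation factor call ended, among others, with the block (adjusted p = 0.0575), without control array 3 (0.317) and without deprived array 4 (0.352), the cholesterol call without control array 4 (0.447) and without both arrays numbered 4 (0.11), and the hypoxia call without control array 4 (0.0628). Without both arrays numbered 4, camera kept the hypoxia call (adjusted p = 0.014). Over all settings the adjusted p ran from 0.00543 to 0.845 for translation factors, from 1.37e-05 to 0.737 for cholesterol synthesis and from 0.000212 to 0.664 for hypoxia targets. With the block camera also called the endoplasmic reticulum genes as lower (adjusted p = 0.0449), but not with an estimated correlation, without the block (0.858) or with it (0.572).

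The series' own subject was the SLC genes, of which 379 were measured. At 5 h 31 of them passed, 21 higher and 10 lower in deprived cells, and 35 passed when adjusted over the list alone (25 higher, 10 lower). Slc7a11, which codes for the light chain of the cystine and glutamate exchanger, rose from 8.38 (SD 0.75) to 11.59 (SD 0.25), a log2 change of 3.21 (SE 0.32; Entrez gene 26570 in the probe table). Slc6a9, a glycine transporter gene, rose 3.41-fold (log2 1.77, SE 0.22), and Slc7a1, which codes for a carrier of cationic amino acids, rose 3.36-fold (log2 1.75, SE 0.25). All 31 differed in the same direction in each of the 4 same-numbered pairs, which is no independent check, since they were selected on these same arrays. Control array 4 was far below the others for Slc6a9, Slc7a1, Slc7a5 and Slc16a9, and without both arrays numbered 4 their changes were 1.56, 1.54, 0.95 and -0.95. For Slc7a11 control array 4 was at 7.29 and the other controls at 8.51 to 8.93. Its change was 2.96 without both arrays numbered 4 and 2.84 without control array 4 alone. The count was 73 with the replicate number as a block (42 higher, 31 lower) and 55 without both arrays numbered 4 (36 higher, 19 lower). Of all 19938 genes, 820 passed in the main fit, 3632 with the block and 2695 without both arrays numbered 4. The SLC share was thus above that of all genes in the main fit but close to it in both other settings. These shares were not tested against each other.

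Amino acid transporters made up 11 of the 21 SLC genes that rose. Of 53 measured genes of this list 11 rose and none fell; adjusted over the list alone, 12 rose. The neutral amino acid carriers Slc1a4 and Slc1a5 rose by 1.19 (SE 0.07) and 1.08 (SE 0.17), and Slc7a5, the large neutral amino acid carrier, by 1.11 (SE 0.13). Slc3a2, the heavy chain that partners with Slc7a5 and Slc7a11, rose by 0.76 (SE 0.08), from a control level of 12.66 (SD 0.12). Of the Slc38 family, Slc38a7 rose by 1.05 (SE 0.14), Slc38a2 by 0.65 (SE 0.07) and Slc38a1 by 0.63 (SE 0.09), and Slc3a1 rose by 0.35 (SE 0.08). Slc7a3, a further cationic amino acid carrier gene, was at 7.29 (SD 0.22) and 7.64 (SD 0.52), a difference of 0.36 (SE 0.23) that did not pass (adjusted p = 0.663 in limma; 0.0297 with the block; 0.0144 to 0.933 over all settings), and that was 0.10 without deprived array 4. Without both arrays numbered 4, the difference of Slc7a3 was 0.21 (adjusted p = 0.0969 in limma). The list's median change was 0.01, its mean 0.25, and camera called it (adjusted p = 3.57e-05) but not with an estimated correlation (adjusted p = 0.434). With the block 15 were higher and 1 lower.

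**Figure D1:**
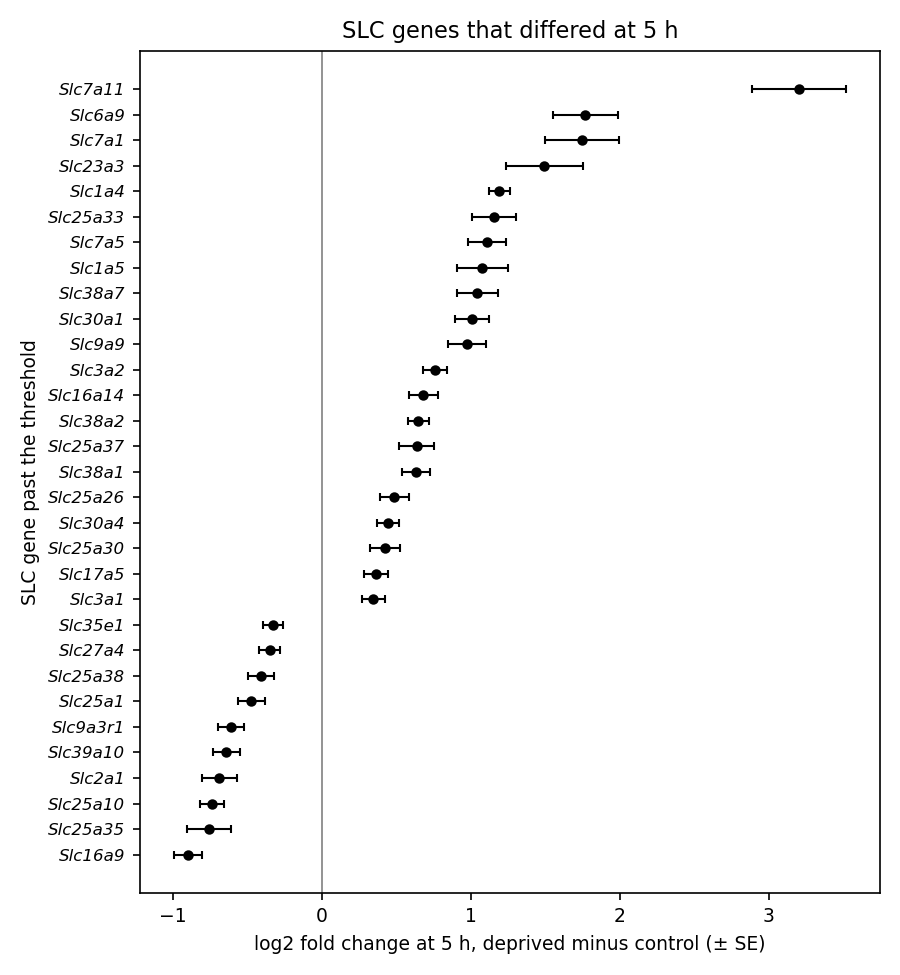
Log2 fold change at 5 h (x axis, deprived minus control, points with SE bars, n = 4 arrays per group) of the 31 SLC genes that passed the threshold (y axis). Slc7a11 stands highest at 3.21 and Slc16a9 lowest at -0.90.

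Other SLC families also held changed members, and the shares of changed members were not compared between families or with all genes. Of 46 mitochondrial carrier genes 4 rose and 4 fell, and 9 were higher and 8 lower with the block. Slc25a33, a pyrimidine nucleotide carrier, rose by 1.16 (SE 0.15), with array 1 highest in both groups, and Slc25a37, an iron carrier known as mitoferrin, by 0.64 (SE 0.12). Slc25a35, Slc25a10 (a dicarboxylate carrier), Slc25a1 (the citrate carrier) and Slc25a38 changed by -0.76 (SE 0.15), -0.74 (SE 0.08), -0.47 (SE 0.09) and -0.41 (SE 0.09). Of 31 zinc and other metal transporter genes Slc30a1, a zinc exporter, rose by 1.01 (SE 0.11), Slc30a4 rose by 0.45 (SE 0.07), and Slc39a10, a zinc importer, fell by 0.64 (SE 0.09); with the block 4 were higher and 2 lower. Slc2a1, the glucose transporter of most cells, fell by 0.69 (SE 0.12) from a level of 12.18 (SD 0.25), and alone passed among 31 sugar transporter genes; 2 were lower with the block.

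Among ion exchangers (55 measured), Slc9a9 rose by 0.98 (SE 0.13) and Slc9a3r1 changed by -0.61 (SE 0.09); the latter fits the SLC naming rule but codes for a scaffold protein. With the block 3 ion exchanger genes were higher and 4 lower. Among 13 monocarboxylate transporter genes Slc16a14 rose by 0.68 (SE 0.10) and Slc16a9 fell by 0.90 (SE 0.10), and 2 were higher and 2 lower with the block. Slc23a3 rose by 1.49 (SE 0.26) and alone passed among 18 nucleoside and vitamin transporter genes; 3 were higher and 1 lower with the block. Slc35e1 (-0.33, SE 0.07) passed of 27 nucleotide sugar transporter genes, against 1 higher and 6 lower with the block. Slc27a4 (-0.35, SE 0.07) passed of 18 lipid and bile acid transporter genes, against 2 lower with the block. Slc17a5 (0.36, SE 0.08) passed of 18 vesicular and phosphate type genes, against 2 higher with the block. None of 40 organic ion transporter genes passed, against 1 lower with the block. Camera called none of these 10 families nor the 379 SLC genes together, whose median change was -0.01 and mean 0.03.

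The next question was how these changes ran over time. The median difference of the amino acid response list was 0.09 at 1 h, 0.47 at 2 h, 0.77 at 3 h, 1.10 at 5 h and 1.23 at 16 h. At each of these times it lay at or above the 99.95th percentile of 10000 random gene lists of the same size and level. This percentile compares genes within the arrays and measures no spread between samples. The list's mean level differed by 0.13 at 1 h and ran from 9.14 to 9.37 among the 5 h controls, so a difference of that size lay within their range. Chac1 and Sesn2 were already higher by 0.74 and 0.77 at 1 h. Slc38a2 was higher by 0.23 at 1 h and 0.68 at 2 h, whereas Slc7a11 differed by -0.07 at 1 h, 0.57 at 2 h, 1.29 at 3 h and 4.21 at 16 h. The list's mean level went from 9.75 at 1 h to 10.36 at 3 h and 10.43 (SD 0.05, n = 4) at 5 h in deprived cells. In control cells it went from 9.61 at 1 h to 9.56 at 3 h, 9.24 (SD 0.09, n = 4) at 5 h and 9.14 at 16 h. The gap thus widened by 1.05 from 1 to 5 h, of which 35.3 percent came from lower values in the controls.

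**Figure D2:**
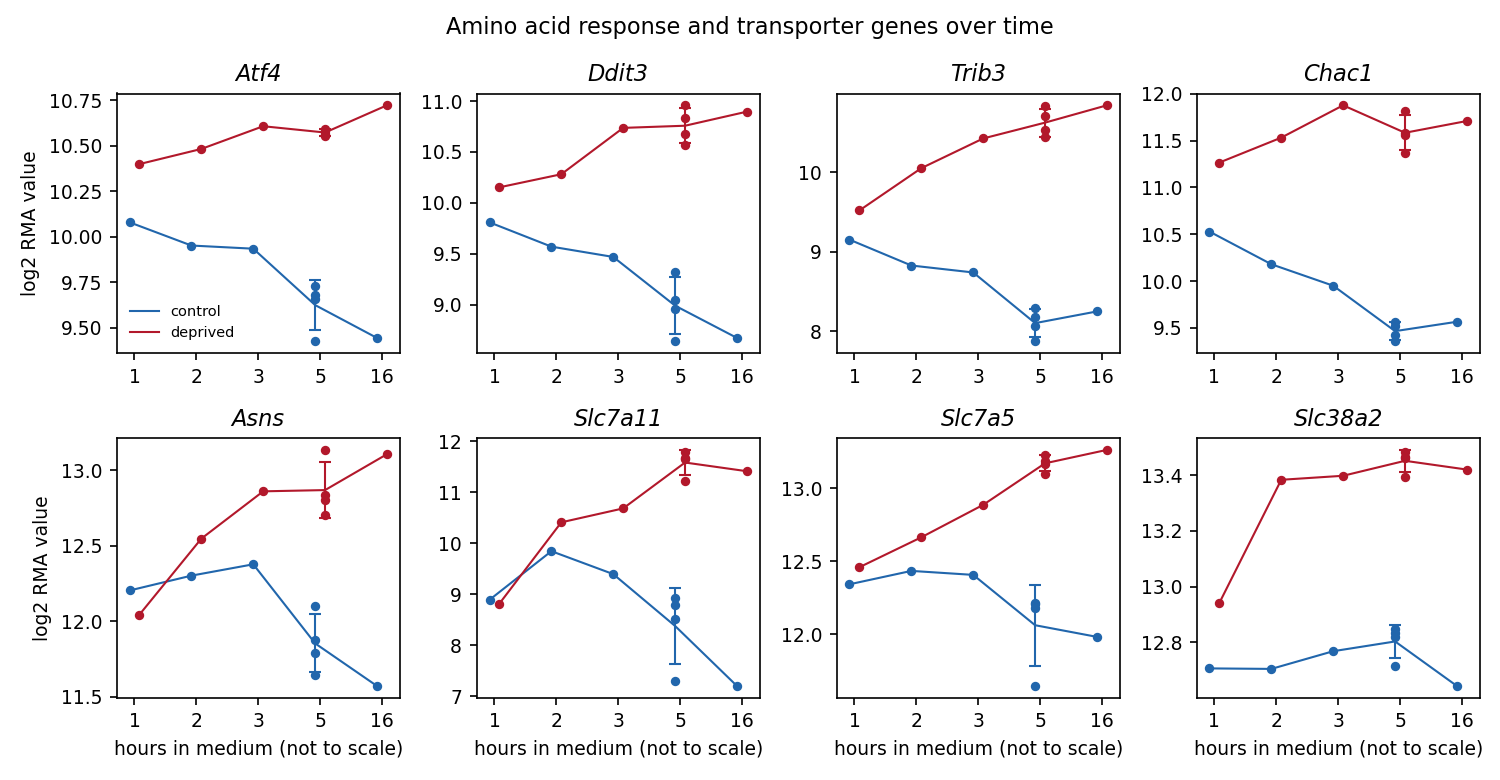
Log2 RMA values (y axes, each with its own range) of 8 genes by hours in medium (x axes, not to scale) in control (blue) and deprived (red) cells; points are arrays, lines join means, and bars at 5 h are SD of 4 arrays. Slc38a2 was 0.68 higher in deprived cells at 2 h, and Slc7a11 4.21 higher at 16 h.

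The cytosolic tRNA synthetases had median differences of -0.09, 0.10 and 0.13 at 1, 2 and 3 h and 1.05 at 16 h, and the serine and one-carbon genes -0.05, 0.06, 0.20 and 0.75. Ribosome biogenesis genes were lower in deprived cells at 1, 2 and 3 h, with medians of -0.12, -0.22 and -0.16, and higher at 16 h with 0.71. Slc30a1 and Slc9a9, which rose at 5 h, differed by -0.12 and -0.02 at 3 h and by 1.10 and 0.93 at 16 h. Of the 31 SLC genes that passed at 5 h, 15 had the same sign at 1 h, 25 at 2 h, 28 at 3 h and 30 at 16 h.

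**Figure D3:**
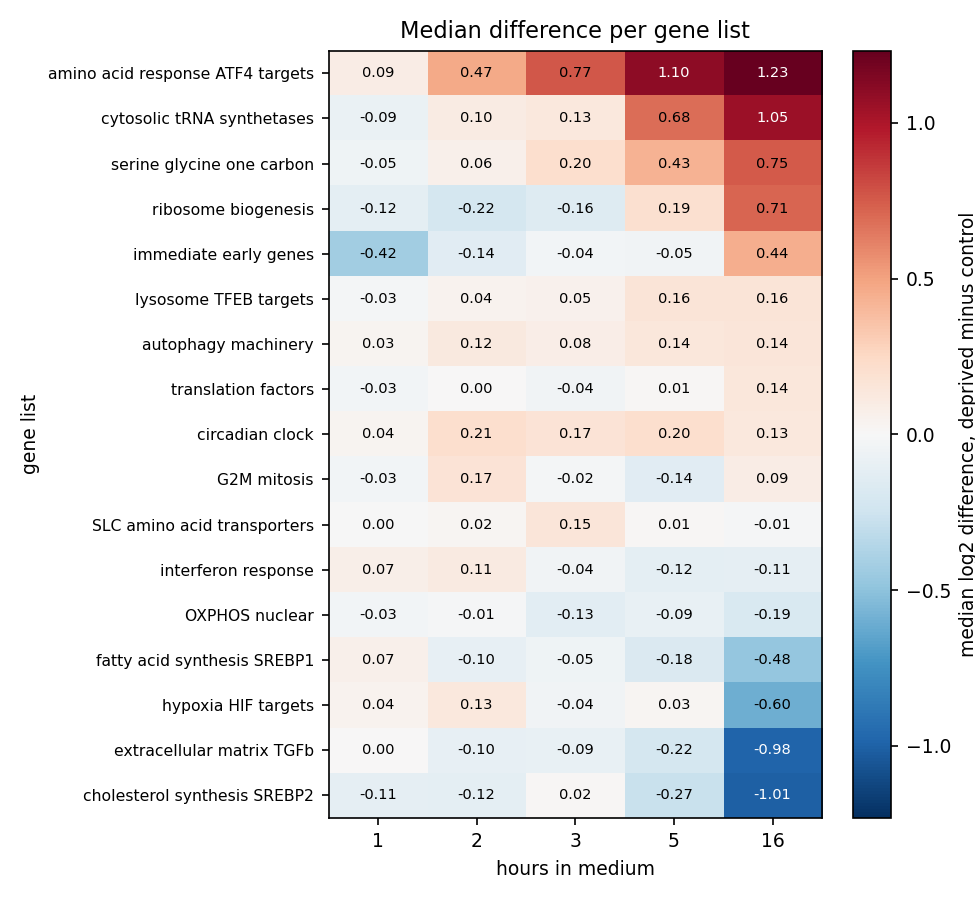
Median log2 difference, deprived minus control (colour and printed value), of 17 gene lists (y axis: the 16 called by camera at 5 h and the immediate early genes) by hours in medium (x axis); 5 h holds 4 arrays per group and the other times 1. The amino acid response list went from 0.09 at 1 h to 1.23 at 16 h, and cholesterol synthesis stood at -1.01 at 16 h.

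At 1 h the 28 immediate early genes, which growth factors induce within minutes, had a median difference of -0.42. Among genes above the median level, to which the rankings at 1, 2, 3 and 16 h are limited, Egr1, an immediate early transcription factor gene, was lowest with -2.50, at levels of 10.52 in the control and 8.02 in the deprived array. Dusp6, a phosphatase that acts on ERK kinases, differed by -2.31, Ereg, a ligand of the EGF receptor, by -1.98, Phlda1 by -1.80 and Arrdc3 by -1.58. At 16 h the median of the immediate early genes was 0.44, and Egr1 was higher by 2.61. Highest above the control at 1 h, again among genes above the median level, were the small RNA genes Snora44 (1.33), Rny1 (1.29), Snord53 (0.97) and Mir145a (0.95), and Sesn2.

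At 2 h Ccng2 (1.45), Hbp1 (1.41), Chac1 (1.35), Gadd45a, a stress-induced gene (1.34), and Sesn2 (1.33) were highest above the control. Aldh3a1 (-1.77), Prickle2 (-1.56), Ereg (-1.34), Ramp3 and Fgf2 (-1.30 each) were lowest. At 3 h the highest were Chac1 (1.93), Trib3 (1.69), Sesn2 (1.60), Atf3 (1.54) and Ppp1r15a (1.33), and the lowest Arrdc3 (-1.65), Has2 (-1.46), Phlda1 (-1.33) and the chemokine genes Ppbp (-1.27) and Cxcl5 (-1.07). A difference of at least 1 was seen for 25 genes at 1 h (4 higher, 21 lower), 36 at 2 h (12 higher, 24 lower) and 27 at 3 h (18 higher, 9 lower). Between replicate arrays at 5 h, 0 to 4 genes lay that far apart among numbers 1 to 3, and 268 to 439 between these and number 4.

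At 16 h the differences were wider. Car6, a secreted carbonic anhydrase gene, was 35.6-fold higher in deprived cells (log2 5.15), Slc7a11 18.5-fold, Avil 12.2-fold (3.61), Cox6a2 8.88-fold (3.15) and Cth 8.18-fold (3.03). Medag (-3.96), Mme, a membrane peptidase gene (-3.89), Aspn (-3.80) and Olfml3 (-3.44), both coding for extracellular matrix proteins, and Angpt1, a ligand of the Tie receptor (-3.48), were lowest. The median difference was -1.01 for the 20 cholesterol synthesis genes, -0.98 for the 24 extracellular matrix genes, -0.65 for the 15 glycolysis genes, -0.60 for the hypoxia targets, -0.48 for fatty acid synthesis and -0.47 for the endoplasmic reticulum genes. Each of these medians lay at or below the 0.12th percentile of random lists, which measures no spread between samples. Astrocyte and radial glia markers had a mean level of 7.84 in deprived and 8.54 in control cells at 16 h, and fibroblast and endothelial markers of 6.83 and 7.44. In the 5 h controls 7 of 14 and 3 of 11 of these markers lay above the median gene. Whether a change in the mix of cells played a part was not tested. Of all genes, 983 differed by at least 1, with 391 higher and 592 lower, or 529 higher and 494 lower when each array was centred on its median.

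Genes changed at 5 h mostly differed in the same direction at 2, 3 and 16 h. Of the 481 genes higher at 5 h, 58.0 percent were higher at 1 h, 86.5 percent at 2 h, 90.9 percent at 3 h and 96.5 percent at 16 h. Of the 339 genes lower at 5 h, 42.5, 85.3, 97.3 and 91.2 percent were lower at these times. Across all genes, which are not independent replicates, the 5 h change correlated with the difference at 1, 2, 3 and 16 h with Pearson's r of 0.016, 0.367, 0.498 and 0.606, and across the 820 genes with 0.128, 0.696, 0.863 and 0.856. The 5 h arrays shared no control with the other times. Without control array 4 the r at 1 h was -0.028.

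**Figure D4:**
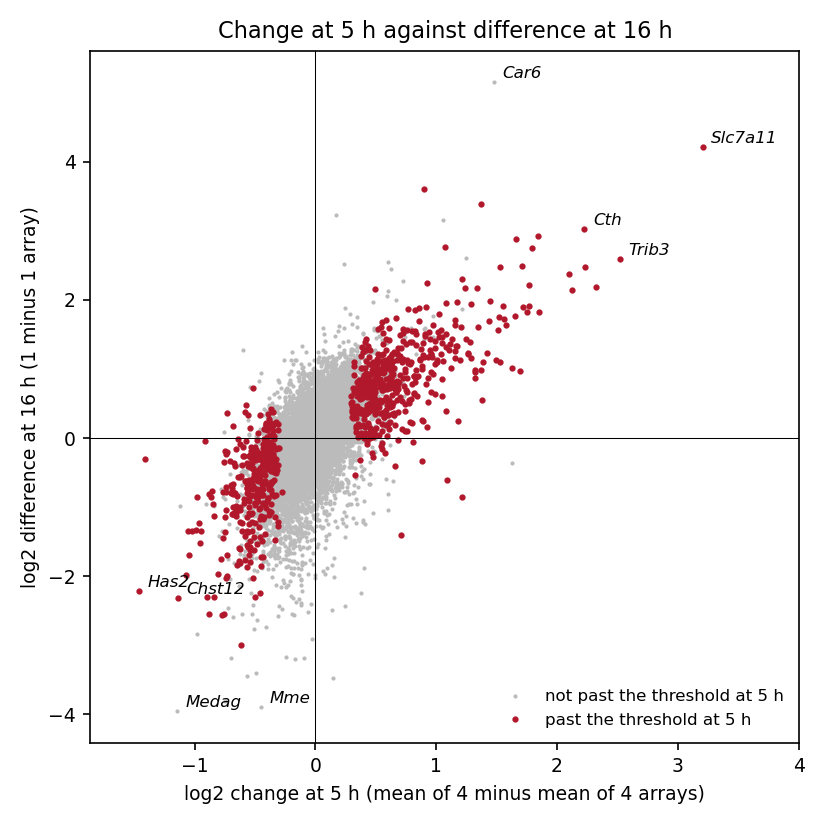
Log2 change at 5 h (x axis, mean of 4 deprived minus mean of 4 control arrays) against the log2 difference at 16 h (y axis, 1 deprived minus 1 control array) for 19938 genes, each a point, with the 820 genes that passed at 5 h in red. Slc7a11 lies at 3.21 and 4.21, and Pearson's r across all genes was 0.606.

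The mean change over the 4 times with 1 array per group was also tested. With time as a factor, limma called 0 genes, against 1244 at an unadjusted p of 0.05. Over 1, 2 and 3 h alone 35 genes passed, 10 higher and 25 lower, and with the 5 h arrays included 1037 passed, 578 higher and 459 lower. Trib3 had a mean difference of 1.47 over the 4 times (SE 0.33) and Chac1 of 1.54 (SE 0.23), and neither passed the threshold.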

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

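The tests on other splits of the arrays, on markers of other cell types and on swapped labels were chosen after the results they concern had been seen. At 5 h, 98 sets of 4 values were examined for a value far from the rest. They were 46 genes and some array measures, each in control and in deprived cells. Of these sets 13 had such a value, and 10 of the 13 were genes on an array numbered 4. Chance would give 4.9 if the sets were independent, but all come from the same 8 arrays, so 4.9 is no proper expectation.

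Both 5 h arrays numbered 4 stood apart from numbers 1 to 3, with many of the same genes in control and deprived cells: 121 genes were at least 1 higher and 77 at least 1 lower on the log2 scale in both groups, including Edil3 (2.99 and 2.90), Col6a3, Col6a1 and Slc40a1 among the higher and Parm1 (-3.38 and -3.30) and Fabp4 among the lower, all named after their values were seen; list medians shifted in both groups for G2 and M phase (0.43 in control, 0.40 in deprived cells) and the proteasome (0.43 and 0.35), but mainly in control cells for cholesterol synthesis (0.43 and 0.07) and the amino acid response (-0.20 and 0.01). A wider spread of values on these arrays is argued against, since after quantile normalization and removal of a trend with level the deviation of number 4 remained at least 2.36 times the largest of the others. A swap of both labels is argued against too, since the difference within number 4 correlated with that of numbers 1 to 3 (r = 0.905 across 2695 genes). Cells of another type stay open: of 5 marker lists the astrocyte list had the highest median, -0.021 in control and -0.004 in deprived cells (upper bound 0.159 for the lower of these), but only 3 of 19 neuron, 7 of 14 astrocyte, 2 of 10 oligodendrocyte, 4 of 13 microglia and 3 of 11 fibroblast and endothelial markers lay above the median gene in these cells, and the brightest markers moved both ways, in control and deprived cells, with S100a4 (1.40 and 1.13), Pdgfra (1.35 and 0.94), Pdgfrb (0.83 and 0.58), Cnp (0.69 and 0.49), Stmn2 (0.52 and 0.66) and Map2 (0.52 and 0.27) higher, Cd68 (-0.56 and -0.90), Slc1a3 (-0.47 and -0.76) and Cx3cr1 (-0.32 and -0.37) lower and Vim near 0 (-0.07 and -0.02). A culture of another passage or day, which the labels do not give, may account for the pattern and was not tested.

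Amino acid response genes were higher in control cells at 1 to 3 h than in the 5 h controls, with list medians of 0.31, 0.36 and 0.33, or 0.26, 0.28 and 0.27 without control array 4; these 3 values share the same 5 h controls, and other lists were also higher there, among them the cytosolic synthetases (0.34, 0.29 and 0.445), cholesterol synthesis (0.675, 0.28 and 0.24), ribosome biogenesis (0.20, 0.39 and 0.53) and serine and one-carbon genes at 3 h (0.36). A drift of the arrays that moves genes of the same level alike is argued against, since each median lay at least 0.188 above the range that held 95 percent of random lists of the same level, and so is a wider spread on the early arrays, since each lay at least 0.278 above the median of such lists. The immediate early genes stood 0.648 above the 5 h controls on the 1 h control array, which is consistent with a response, shared by both lists, to a change of medium, a step the labels imply but do not describe. That list stood only 0.13 above at 2 h and 0.05 at 3 h, so the courses differ, and no array from before the treatment was analysed here. Growth of the culture over the hours stays open as a biological explanation and was not tested.

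Single values far from the rest of their group, with the gap as a share of the range, were the mean correlation with other arrays of deprived array 4 (0.918), and, lowest on control array 4, Atf3 (0.867), Slc6a9 (0.858), Slc7a1 (0.913), Slc7a5 (0.933) and Slc16a9 (0.881). On deprived array 4, Ccne1 (0.833) and Slc7a1 (0.844) were lowest and Slc7a3 (0.858) highest, and Ddit4 was highest on array 4 in control (0.844) and deprived (0.895) cells. Slc25a33 was highest on array 1 in both groups (0.895 and 0.971).

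Differences between times, none of them tested, were seen for Ddit4, which was 0.64 higher in deprived cells at 5 h but differed by -0.94 at 1 h and -0.61 at 16 h. The G2 and M phase list had a median of 0.165 at 2 h against -0.14 at 5 h, and the ribosome biogenesis list had medians of -0.118, -0.216 and -0.159 at 1, 2 and 3 h against 0.19 at 5 h.

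Rows outside the tested genes also differed at 5 h in limma. Of 1621 rows with several symbols 21 passed (9 higher, 12 lower), and of 5529 unnamed rows among the named numbers 40 passed (29 higher, 11 lower). Of 6617 unnamed rows with lower numbers 114 passed, 107 higher and 7 lower, with changes of up to 2.35.

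Of the 35 splits of the 8 arrays, 4 against 4, only the real 1 gave as many as 820 genes or 31 SLC genes. The highest of the others gave 0. With a share under 0.05, this argues against chance for these counts only if the arrays are taken as unpaired. That condition is doubtful, since the deviations of the arrays numbered 4 correlated with 0.896. Only 8 of these splits part all 4 same-numbered pairs, as the real 1 does, and the others leave some pairs whole; with 820 and 31 against a highest other of 0, and 3632 against 0 in the blocked fit, these 8 are too few for a share under 0.05. Chance as the source of the number of camera calls cannot be excluded, since 11 of 35 splits gave as many as the real 16 lists and the highest other gave 20. For the mean over the times with 1 array per group, the real value was 0 and the highest other 0, and all 8 splits gave as many, which are too few for a share under 0.05.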

How the results depend on the processing

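The setting without both arrays numbered 4 and the estimated correlation in the blocked fit were chosen after the data were seen; the cause of a changed value was not tested unless stated. The 820 genes at 5 h became 3632 with the replicate block, 5485 with array weights, 2695 without both arrays numbered 4 and 335 with a 1.5-fold minimum, which by construction keeps fewer genes. All 820 were among the 3632, the 5485 and the 2695. In the fit with array weights, control array 2 had a weight of 10.6 and the other controls 0.83, 0.71 and 0.14. All counts from that fit thus rest mostly on 1 control array. With 1 array left out the count was 382 to 1066, and in the other 8 settings with all arrays 754 to 1229. The 31 SLC genes became 73 with the replicate block, 97 with array weights and 55 without both arrays numbered 4, and were 21 to 33 with 1 array left out. The 16 lists became 1 with an estimated correlation, 0 with that and the replicate block together and 10 with fry, which left out 7 of the 16 and added the astrocyte and radial glia markers (adjusted p = 0.0173), and were 13 to 18 with 1 array left out. The replicate block alone gave 19 lists, ended the translation factor call and added the endoplasmic reticulum, heat shock, proteasome and NF-kB lists. Among the 14 genes always named it changed only the calls of Ddit4 and Slc7a3. The count of 0 genes over the times with 1 array per group became 35 for 1, 2 and 3 h only, and 1037 with all 16 arrays and time as a factor, which adds the 8 arrays of 5 h. The correlation of the 5 h change with 1, 2, 3 and 16 h ran from -0.028 to 0.07, 0.302 to 0.397, 0.397 to 0.571 and 0.536 to 0.622 with 1 array left out. It was 0.444 at 2 h and 0.625 at 3 h for genes above the median level, 0.557 at 16 h without both arrays numbered 4, and 0.128, 0.696, 0.863 and 0.856 over the genes past the threshold. The counts of genes at least 1 apart at 1, 2, 3 and 16 h stayed within 1.5 times in the 3 other settings. Of 320 values of the called lists under other settings 268 kept their call and 52 lost it, 31 of these with an estimated correlation; the highest adjusted p was 0.17 for the amino acid response and 0.453 to 0.868 for the other 15 lists, and of 237 values of the always named genes 232 kept their side of the threshold and 5 gained a call. The setting with all 16 arrays is counted in both tallies, though for genes it must repeat the main calls. No called list or always named gene changed direction while called. The balance of calls at 5 h, 481 higher and 339 lower, turned to more lower than higher genes with the replicate block (1639 and 1993), with array weights (2610 and 2875) and without both arrays numbered 4 (1265 and 1430), and that at 16 h from 391 higher and 592 lower to 529 and 494 with centring. Detection calls were not analysed here, so how far background limits the genes with the lowest signal is open.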

Other observations

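Lists of growth and stress genes not described so far held the following changes at 5 h in limma. Of 28 immediate early genes Klf4 and Myc, both transcription factor genes, rose by 1.42 (SE 0.21) and 1.34 (SE 0.18) and Ccn1 fell by 0.50 (SE 0.12), and with the replicate block 6 were higher and 10 lower. Of 16 p53 target genes Gadd45a rose by 1.72 (SE 0.15), Eda2r by 1.18 (SE 0.11) and Trp53inp1 by 0.93 (SE 0.07), while 3 fell, including Sesn1 (-0.73, SE 0.16). In this list 4 were higher and 7 lower with the block. Trp53inp1 belongs to the amino acid response list as well. Of 40 S phase genes Cdt1, a licensing factor of replication, rose by 0.68 (SE 0.13), and Ccne1 and Rrm2, a subunit of ribonucleotide reductase, fell by 0.98 (SE 0.11) and 0.35 (SE 0.08); 8 were higher and 4 lower with the block. Of 21 histone genes H2bc4 fell by 0.68 (SE 0.10). None of 34 genes of G2 and M phase passed, with a median of -0.14, against 13 lower with the block. Of 19 genes of the oxidative stress response Nqo1 and Srxn1 fell by 0.63 (SE 0.13) and 0.34 (SE 0.08), against 3 higher and 5 lower with the block. Of 13 heat shock genes Bag3 fell by 0.63 (SE 0.13), against 5 lower with the block. Of 22 FOXO target genes Sesn1 fell, against 7 higher and 5 lower with the block.

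Of 17 interferon response genes Ifit3 and Gbp3 fell by 0.57 (SE 0.13) and 0.47 (SE 0.09), against 8 lower with the block. None of 20 NF-kB target genes passed, against 6 lower with the block, nor did any of 24 extracellular matrix genes, with a median of -0.22, against 8 lower with the block, or of 34 oxidative phosphorylation genes, with a median of -0.09, against 8 lower with the block. Of 29 proteasome genes Psmc6 rose by 0.49 (SE 0.09), against 1 higher and 4 lower with the block, and none of 54 ribosomal protein genes passed in either fit. Of 14 astrocyte and radial glia markers Gja1, a gap junction gene, and Nes, nestin, fell by 0.76 (SE 0.08) and 0.69 (SE 0.12), and 3 were lower with the block. None of 27 hypothalamic neuropeptide and receptor genes, 19 neuron, 10 oligodendrocyte, 13 microglia or 11 fibroblast and endothelial markers passed, against 2 higher, 1 higher, 2 lower, 2 lower and 0 with the block.

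Of these lists camera called G2 and M phase, oxidative phosphorylation, interferon and extracellular matrix genes as lower, with adjusted p = 0.00154, 0.00341, 0.00531 and 0.000282. With an estimated correlation the adjusted p was 0.868, 0.67, 0.286 and 0.136, and the calls of the first pair also ended without control array 4 (adjusted p = 0.452 and 0.235). Over all settings the adjusted p ran from 9.05e-07 to 0.868, from 2e-05 to 0.67, from 0.00257 to 0.572 and from 1.6e-05 to 0.572. The calls of G2 and M phase and oxidative phosphorylation held without both arrays numbered 4 (camera adjusted p = 0.000185 and 0.00156). With the block they held too (camera adjusted p = 2.21e-05 and 0.00122). Leaving out control array 4 alone keeps deprived array 4, where both list medians were also raised (0.40 and 0.25). With the replicate block camera also called the heat shock (0.02), proteasome (0.0166) and NF-kB (0.036) lists as lower. None of these was called with an estimated correlation, without the block (adjusted p = 0.992, 0.992 and 0.575) or with it (0.572, 0.796 and 0.572). Median and mean differed in sign for the immediate early (-0.05 and 0.06), nutrient sensing (-0.04 and 0.01), S phase, neuropeptide and neuron lists, and for all SLC genes, the mitochondrial, nucleotide sugar and nucleoside SLC families; camera's direction differed from both for the vesicular SLC family.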
